A study of Homo sapiens with 4 samples.

How the data were processed

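RNA sequencing was run on 4 libraries of U2OS cells, an established human osteosarcoma cell line. Per the labels, 2 libraries came from cells given a control single-domain antibody (sdAb) and 2 from cells given an sdAb against MN1. A single-domain antibody is a small antibody fragment that consists of one variable domain. The dose, the exposure time and the way the antibody reached the cells are not given in the sources used here. Total RNA was taken with Trizol, per the labels' protocols. Whether the libraries of a group came from separate cultures is not given either, so the p-values measure the spread between these libraries, which may be technical.

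The authors deposited 1 table of read counts per gene, with 58676 Ensembl gene identifiers and no gene names. The counts are whole numbers with no normalization, as read from the values, and sum to between 15740268 and 16816893 per library, so a count of 0 allows up to 0.178 to 0.191 CPM at 3 counts, for counting error only. The submitters' processing notes name Bowtie2, HTSeq and the human build hg38 (GRCh38). Their versions, their order and roles, the annotation release and the strand setting are not given in the sources used here. The columns were matched to libraries by the first letter of the group and the replicate number in the sample titles. All 58676 identifiers were present in GENCODE release 29, which is on GRCh38, and coordinates and gene types were taken from it. Current symbols were available for 58207 identifiers, and the others kept their GENCODE name. No count was found in any library for 24438 identifiers.

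The counting was checked for overlapping genes, since the strand setting is not given. Of 11070 protein-coding genes with no exon overlap, 14.2% had no count in any library. Of 424 genes overlapped by other genes' exons on the same strand over 90% or more of their exonic bases, 87.0% had none, and of 25 genes overlapped that far on the opposite strand, 80.0% had none. Genes that overlap others, on either strand, may therefore be undercounted here. The share of each named gene's sequence found in other genes was measured with windows of 50 bases from its longest transcript.

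Genes were tested in R (version 4.3.3) with edgeR (version 4.0.16). Low-count genes were removed with filterByExpr at its default minimum count of 10, which left 17524 genes holding 99.8% of the counts of each library. Library sizes were scaled by the trimmed mean of M values (TMM), with factors from 0.971 to 1.03. The quasi-likelihood test compared the groups with no covariate and was 2-sided. It was adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Each gene's spread was drawn toward that of all genes, with a median of 209 prior degrees of freedom. With 2 libraries per group, the p-values thus rest mostly on this shared spread. Levels are TMM-scaled CPM, the usual read count relative to library size, given as mean ± SD over the 2 libraries of a group. Fold changes are anti-MN1 over control, and their standard error is the size of the log2 fold change divided by the square root of the test statistic. On simulated counts with the real means, depths and dispersions (17093 genes tested), the test called 16 of 71 genes changed 1.2-fold, 41 of 61 changed 1.5-fold and 45 of 63 changed 2-fold. Among simulated genes with a mean of at least 5 CPM it called 39 of 45 changed 1.5-fold and all 38 changed 2-fold. It called 7 of 16898 unchanged genes. Only a small part of the genes was changed there, against 7942 called in the real data. The adjustment is stricter when few genes change, so these rates do not carry over to the real data.

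The choices that follow were made before the data were examined. The named genes are MN1, then the 12 with the largest rise and the 12 with the largest fall among genes past the threshold with a mean CPM of at least 5, a proper gene symbol, no pseudogene, and both anti-MN1 libraries beyond both control libraries. From each gene list up to 4 members with the smallest p were named. Some of these genes are not reported here. The 44 lists covered MN1 partners and programmes, cell cycle, stress, signalling, matrix, metabolism, RNA classes and markers of other cell types. They were tested with camera (limma version 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 44 lists. camera asks whether a list's genes moved more than the other genes. On simulated counts it called a list raised 1.3-fold and 0 of 40 unchanged lists. Genes were drawn independently there and no other gene was changed, so false calls among correlated genes were not measured. Alternatives were camera with an estimated correlation, fry (which tests a list's own genes), other scalings and filters, DESeq2 (version 1.42.0), limma-voom, removal of the 20 most abundant genes, a block on the replicate number and leaving out each library. With an estimated correlation, camera draws its degrees of freedom from the few libraries. Few lists can then pass, and a lost call decides little.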

Results

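The data were gene-level read counts from 4 U2OS libraries, 2 from cells given the control sdAb and 2 from cells given the anti-MN1 sdAb. The control libraries held 15740268 and 16816893 counts and the anti-MN1 libraries 16075169 and 15970324. Libraries of a group were close to each other, with Pearson's r across genes on log2 CPM of 0.992 for the controls and 0.990 for the anti-MN1 libraries, against 0.973 to 0.974 between groups. The libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 2.21 for the controls and 1.98 for the anti-MN1 libraries, and all 4 were kept as separate samples. The first principal component separated the groups and held 73.5% of the variance.

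The single comparison of the design asks which transcripts differ in U2OS cells given the anti-MN1 sdAb rather than the control sdAb. By camera at the preset correlation, the lists of interferon-stimulated, inflammatory cytokine and antioxidant genes were higher than other genes with the anti-MN1 sdAb, and those of histone, mitochondrially encoded and fibrillar matrix genes (11 of 22 fell and 5 rose) were lower. Each of these 6 calls was lost with an estimated correlation (adjusted p = 0.41). Among genes with a mean of at least 5 CPM, the largest rise was in ESM1, which encodes the secreted proteoglycan endocan, from 4.93 ± 0.309 to 123 ± 2.64 CPM (SD, n = 2 per group). Among the largest falls were those of CXCL14, a chemokine gene, from 37.7 ± 1.68 to 3.79 ± 1.06 CPM, and DRD1, a dopamine receptor gene, from 10.7 ± 0.949 CPM to 0.448 and 1.23 CPM. The log2 fold change of DRD1 was -3.67, and -4.55 without anti-MN1 replicate 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4153 genes rose and 3789 fell among 17524 tested. Most of these changes were small, since 4948 of the 7942 were under 1.5-fold. At least 2-fold changes were found in 334 genes that rose and 1198 that fell, and a test against a change of 1.5-fold called 358 higher and 815 lower. The split between higher and lower genes depended on the scaling, with 52.3% of the called genes higher under TMM and 38.0% under upper-quartile factors (3058 higher and 4985 lower). The split also differed by RNA type, with 3951 protein-coding genes higher and 3094 lower, against 59 and 240 long intergenic non-coding RNAs, 39 and 148 antisense RNAs and 3 and 57 unprocessed pseudogenes. It differed by level as well, with 233 genes higher and 889 lower at a mean of 1 to 5 CPM. At 100 CPM or more, 1228 were higher and 463 lower. The RNA types were not compared at equal levels. DESeq2 called fewer genes lower (2338, with 779 at least 2-fold lower).

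**Figure D1:**
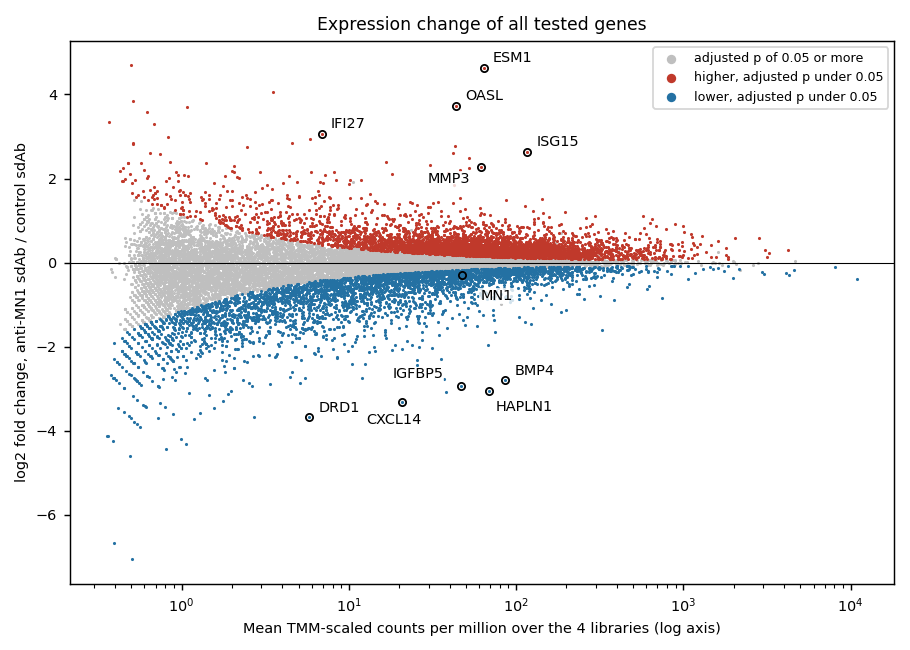
Log2 fold change (anti-MN1 over control sdAb) of 17524 tested genes against their mean TMM-scaled CPM on a log axis. Red and blue points passed the edgeR test and grey points did not; MN1 lies near the centre at -0.30, and ESM1 is the highest labelled gene at 4.64.

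MN1 itself, the gene of the antibody's target protein and a transcriptional coregulator, was expressed in all 4 libraries (ENSG00000169184, chromosome 22, 27748277 to 27801498, minus strand, GRCh38). Its level was 52.5 ± 0.113 CPM in the controls and 42.8 ± 1.34 CPM with the anti-MN1 sdAb (SD, n = 2 per group). This was a log2 fold change of -0.30 ± 0.07 (SE) with an adjusted p of 0.000306 in edgeR. The change of MN1 stayed below 1.5-fold. The 135 tested genes on chromosome 22 from 20 to 30 Mb, where MN1 lies, had a median log2 fold change of -0.30. The fall of MN1 was thus no larger than the median of its region, and a fall specific to MN1 was not shown. An antibody binds the protein, so the transcript does not check the labels. Of 15 measured genes of MN1 and its partners, 3 rose and 6 fell, and the list as a whole did not pass camera (adjusted p = 0.66). The nuclear receptor coactivator genes NCOA1 and NCOA2 fell by 0.51 and 0.29 on the log2 scale. RING1, a Polycomb ubiquitin ligase gene, fell by 0.31. In the HOX programme described in MN1 leukaemia, 2 of 14 measured genes rose and 3 fell (camera adjusted p = 0.69). SPARC, which encodes a matrix glycoprotein, fell 2.25-fold there and PBX3 1.43-fold, while MECOM rose 1.34-fold and IGFBP7 1.53-fold. The call of IGFBP7 was lost with DESeq2.

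Of the 12 genes with the largest rises, 8 belonged to the list of interferon-stimulated genes. OASL (chromosome 12, 121019111 to 121039242), an oligoadenylate synthetase-like antiviral gene, rose from 6.10 ± 0.295 to 81.3 ± 5.39 CPM. ISG15, a ubiquitin-like modifier, rose from 32.3 ± 2.49 to 201 ± 0.0507 CPM. IFI27 rose 8.35-fold, IFIT2 6.80-fold, IFIT3 6.07-fold, IFI6 5.64-fold, HERC5 4.96-fold and IFI44 4.78-fold. ESM1 (chromosome 5, 54977864 to 55022671) had a log2 fold change of 4.64 ± 0.09 (SE), with an adjusted p of 3.73e-116 in edgeR. NT5E, the ecto-nucleotidase CD73, rose 7.62-fold from 1.35 CPM, and MMP3, the matrix protease stromelysin, 4.83-fold from 21.3 CPM. KRTAP2-3, a keratin-associated protein gene, rose 5.22-fold, but 38.6% of its sequence windows occur in other genes and its level is uncertain.

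Among the 12 largest falls, BMP4, a bone morphogenetic protein gene (chromosome 14, 53949736 to 53958761), fell from 151 ± 1.73 to 21.8 ± 0.257 CPM, a log2 fold change of -2.79 ± 0.06 (SE) with an adjusted p of 2.33e-103 in edgeR. IGFBP5 (chromosome 2, 216672105 to 216695525), an insulin-like growth factor binding protein gene, fell from 82.9 ± 0.962 to 10.9 ± 1.61 CPM. HAPLN1, a hyaluronan link protein gene, fell 8.37-fold from 122 CPM, and CXCL14 fell 9.92-fold. The meiosis gene SHOC1 fell 8.48-fold and the zinc finger gene ZNF608 6.83-fold. MAF, a leucine zipper transcription factor gene, fell from 20.8 ± 0.380 to 3.11 ± 1.84 CPM, a log2 fold change of -2.74, and of -3.51 without anti-MN1 replicate 1. CSDC2 fell 5.44-fold, GUCY1A2, a guanylate cyclase subunit gene, 5.34-fold and BPIFB4 6.73-fold. The glucose transporter gene SLC2A12 fell 7.27-fold, with 38.9% of its exonic bases shared with genes on the other strand. All 24 of these genes kept their call and direction in every alternative run, DESeq2 and limma-voom included.

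**Figure D2:**
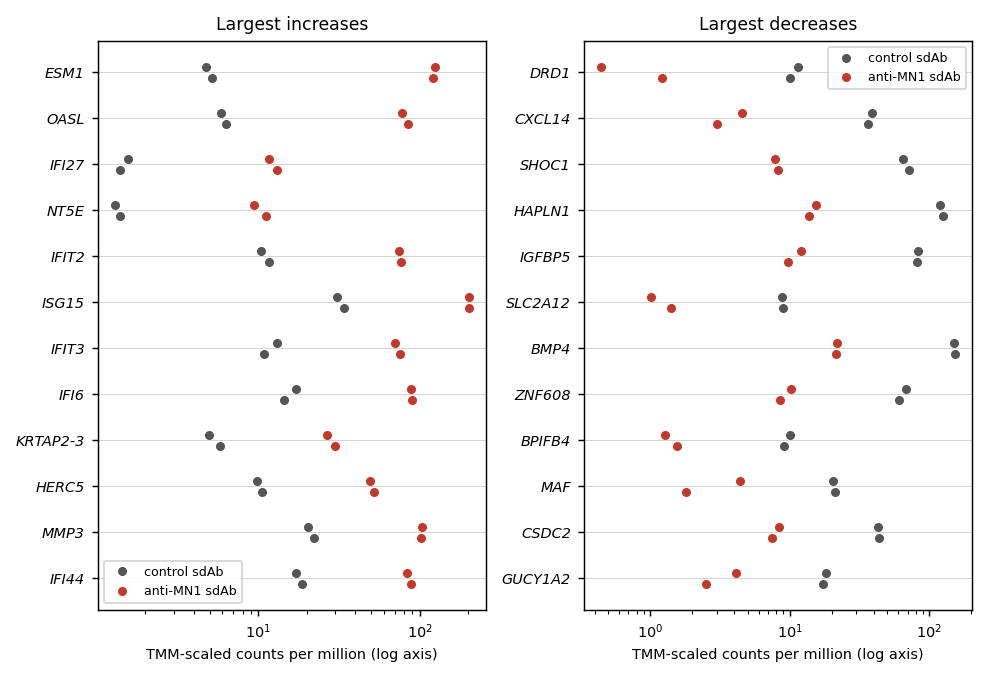
TMM-scaled CPM of each library (log axis) for the 12 genes with the largest rises and the 12 with the largest falls, 1 point per library, 2 libraries per group. The genes were chosen so that both anti-MN1 libraries lie beyond both control libraries, as in 12394 of the 17524 tested genes (70.7%).

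Of 32 measured interferon-stimulated genes, 26 rose and 0 fell, and 22 of them rose at least 2-fold. The list's median log2 fold change was 1.53 (camera adjusted p = 1.80e-19). With an estimated correlation this call was lost (adjusted p = 0.41). Among the 6 members that did not pass were STAT2, IRF1, IRF7 and IRF9, which encode transcription factors of the interferon response, at log2 fold changes from -0.07 to 0.26. They were named after their values were seen, and all of IRF9's sequence windows occur in other genes. Of 15 antigen presentation genes, 9 rose and 1 fell, led by B2M, the light chain of major histocompatibility complex class I, which rose from 857 ± 12.3 to 1376 ± 36.2 CPM. The trimming peptidase gene ERAP1 rose 1.41-fold and the peptide transporter gene TAP2 1.55-fold. The list passed camera (adjusted p = 0.00211; adjusted p = 0.41 with an estimated correlation). The 19 fixed blood markers together stood at 30.1 and 31.7 CPM in the controls and at 49.8 and 47.2 CPM in the anti-MN1 libraries. Summed over 18 blood markers without LCP1, which was left out after its values were seen, the level was 6.80 and 7.40 CPM in the controls and 5.32 and 4.34 CPM in the anti-MN1 libraries, while LCP1, an actin-bundling gene, rose 1.82-fold from 24.0 CPM.

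Of 23 NF-kB and inflammatory cytokine genes, 15 rose and 2 fell (camera adjusted p = 0.000101; adjusted p = 0.41 with an estimated correlation). IL6 rose from 1.11 ± 0.073 to 8.01 ± 1.28 CPM and the chemokine genes CXCL8 and CCL2 rose 2.89-fold and 2.28-fold. TNFAIP3, a feedback inhibitor of NF-kB, rose 1.87-fold. Of 23 ERK and immediate early genes, 14 rose and 2 fell (camera adjusted p = 0.000872; adjusted p = 0.47 with an estimated correlation). The phosphatase gene DUSP4 rose 2.71-fold, FOSL1 1.96-fold, KLF4 1.84-fold and the receptor gene EPHA2 1.35-fold. EGR2, an early growth response gene named after its value was seen, fell from 3.09 to 0.610 CPM. Of 21 apoptosis regulators, 11 rose and 2 fell (camera adjusted p = 0.0418; adjusted p = 0.45 with an estimated correlation). The risers included the anti-apoptotic genes MCL1, from 290 to 411 CPM, BCL2A1, from 0.383 to 6.62 CPM, and BIRC2, up 1.53-fold. BCL2A1 had a log2 fold change of 4.06, and of 5.10 without control replicate 2. The pro-apoptotic gene BMF fell 2.23-fold.

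Of 19 NRF2 target genes, which encode antioxidant and detoxifying proteins, 17 rose and 1 fell (camera adjusted p = 8.74e-14; adjusted p = 0.41 with an estimated correlation). TXNRD1, thioredoxin reductase, rose from 766 ± 6.76 to 1263 ± 0.536 CPM. The aldo-keto reductase genes AKR1C2, AKR1C3 and AKR1C1 rose 1.90-fold, 1.73-fold and 1.64-fold, and 52.6% of the AKR1C2 windows occur in other genes, so reads may be split among these relatives. Of 17 heat shock genes, 14 rose and 2 fell (camera adjusted p = 1.47e-06; adjusted p = 0.41 with an estimated correlation). HSP90AA1 rose from 1616 ± 35.1 to 2431 ± 57.5 CPM and HSPA8 1.42-fold. HSPA1A and HSPA1B, near-identical copies whose separate counts are uncertain, rose by 0.68 and 0.86 on the log2 scale. CRYAB, a small heat shock protein gene named after its value was seen, fell by 1.93 on the log2 scale.

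**Figure D3:**
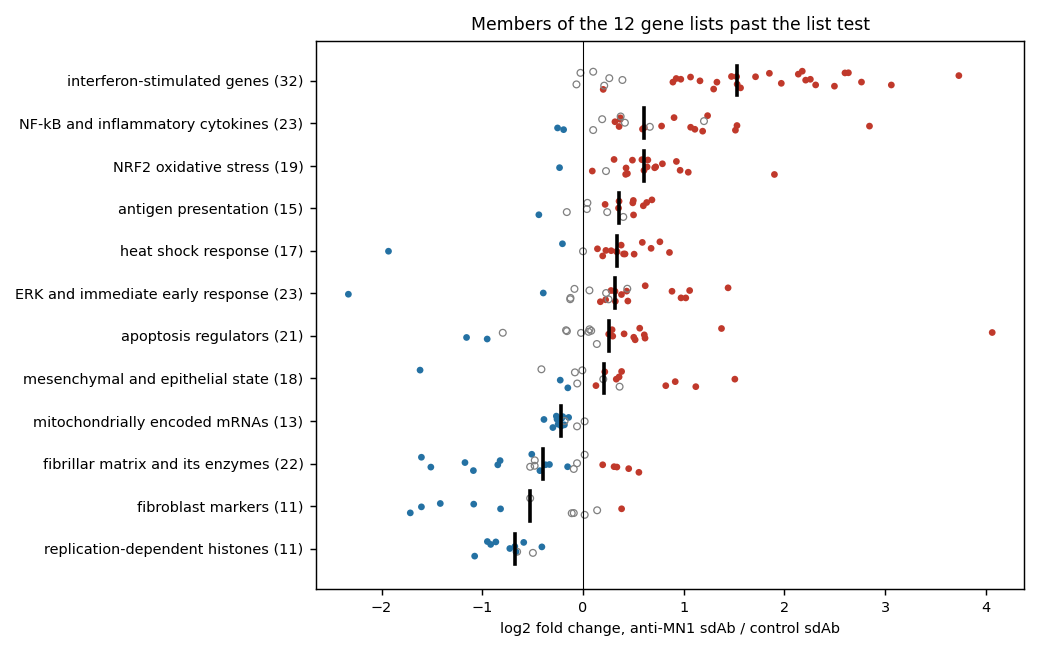
Log2 fold changes (anti-MN1 over control sdAb) of the measured members of the 12 gene lists that passed camera at the preset correlation, with the number of members in brackets. Filled points passed edgeR's test (red higher, blue lower), open points did not, and black bars are medians, from 1.53 for interferon-stimulated genes to -0.68 for histones.

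Of 22 measured fibrillar matrix genes, 5 rose and 11 fell (camera adjusted p = 0.00226; adjusted p = 0.41 with an estimated correlation). COL1A1, the main chain of type I collagen, fell from 493 ± 12.1 to 162 ± 3.81 CPM, and SPARC, COL6A1 and COL6A2 fell 2.25-fold, 2.13-fold and 1.80-fold. COL3A1, another fibrillar collagen gene named after its value was seen, was at 0.02 on the log2 scale. Of 11 fibroblast markers, 1 rose and 5 fell (camera adjusted p = 0.0172; adjusted p = 0.45 with an estimated correlation). PDGFRB fell 3.28-fold and THY1 1.76-fold and S100A4 rose by 0.38 on the log2 scale. COL1A1, COL3A1, DCN and LUM belong to both lists. Of 18 genes of mesenchymal and epithelial state, 9 rose and 3 fell (camera adjusted p = 0.0418; adjusted p = 0.45 with an estimated correlation). The adhesion genes ITGA2 and CD44 rose 2.84-fold and 2.17-fold and ITGA5 1.28-fold.

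Replication-dependent histone genes fell, with 0 of 11 higher and 9 lower (camera adjusted p = 3.04e-05; adjusted p = 0.41 with an estimated correlation). H1-2 fell 1.82-fold to 52.2 ± 1.23 CPM, and H2AC6, H2BC21 and H2BC12 fell 1.93-fold, 2.11-fold and 1.33-fold, with 76.5% of the H2BC12 windows found in other genes. Of the 13 mitochondrially encoded mRNAs, 0 rose and 10 fell, by small amounts (camera adjusted p = 7.34e-07; adjusted p = 0.41 with an estimated correlation). MT-CO1, a cytochrome c oxidase subunit gene, fell from 12359 ± 718 to 9445 ± 106 CPM, and MT-ND4, MT-CO2 and MT-CO3 fell by 0.30, 0.26 and 0.25 on the log2 scale. From 29.7% to 49.3% of the windows of MT-CO1, MT-CO2 and MT-CO3 occur in other genes, which leaves their levels uncertain. Mitochondrial genes took 4.45% and 4.31% of all counts in the controls and 3.40% and 3.49% in the anti-MN1 libraries. The share of long intergenic non-coding RNAs moved the same way, at 0.831% and 0.826% in the controls and 0.712% and 0.694% in the anti-MN1 libraries.

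The other 32 lists did not pass camera, and their members mostly went both ways. Proliferation genes were of this kind, with 9 of 35 G1/S and DNA replication genes higher and 8 lower, and 10 of 35 G2/M genes higher and 11 lower. TK1 fell 1.33-fold and RRM2, RRM1 and CDC6 rose 1.17-fold to 1.21-fold, while TOP2A and DLGAP5 fell by 0.38 and 0.34 on the log2 scale and ASPM and PLK1 rose 1.25-fold and 1.27-fold. Of 16 cyclin and CDK genes, 6 rose and 4 fell, with CCND3 up 2.08-fold, CDKN2A 1.52-fold, CDK6 1.36-fold and MYC 1.51-fold. Of 23 p53 targets, 5 rose and 8 fell, with PMAIP1 up 1.65-fold and TP53INP1 down 1.72-fold. Of 21 DNA repair genes, 6 rose and 4 fell, and of 21 BAF subunit genes, 5 rose and 5 fell. SMARCC2 fell 1.32-fold and BRD9 rose 1.29-fold.

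Among the signalling lists, 4 of 16 Wnt genes rose and 8 fell (camera adjusted p = 0.0695), with the feedback genes AXIN2 and NKD1 down 3.92-fold and 3.38-fold, DKK3 down 1.82-fold and WNT5A up 1.61-fold. Of 19 TGF-beta genes, 9 rose and 6 fell, with TGFB2 down 3.12-fold and CCN2 up 1.66-fold. Counts of higher and lower genes were 9 and 4 of 18 YAP targets, 7 and 3 of 12 Notch genes, and 5 and 5 of 19 PI3K genes, where IRS1 fell 1.85-fold and IRS2 rose 1.80-fold. Of 21 growth factor and receptor genes, 11 rose and 5 fell, with FGF2 up 2.11-fold, EGFR 1.89-fold and MET 1.54-fold and IGFBP5 down as above. In the osteoblast list, 3 of 12 rose and 4 fell, with the transcription factor gene RUNX2 down 1.79-fold, BMP4 down as above, and TNFRSF11B and BMP6 up by 0.59 and 0.67 on the log2 scale. Of 9 vitamin D receptor targets, 2 rose and 3 fell. CYP24A1, the vitamin D 24-hydroxylase, fell 2.46-fold and CLMN 1.65-fold, while G0S2 rose 3.77-fold from 2.80 CPM and HBEGF by 0.68 on the log2 scale. Of 11 retinoic acid targets, 3 rose and 6 fell. Of 16 matrix protease genes, 7 rose and 4 fell.

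Among the stress and metabolic lists, higher and lower counts were 10 and 4 of 20 unfolded protein response genes, 7 and 15 of 29 integrated stress genes, and 10 and 8 of 33 hypoxia and glycolysis genes. They were 11 and 7 of 24 cholesterol synthesis genes and 5 and 8 of 18 fatty acid and LXR genes, where the desaturase gene FADS2 fell 2.46-fold and CPT1A rose by 1.05 on the log2 scale. They were 6 and 4 of 29 nuclear oxidative phosphorylation genes, 8 and 4 of 24 lysosomal genes, where the autophagy receptor gene SQSTM1 rose 2.15-fold, and 4 and 1 of 6 metal response genes. Of 40 ribosomal protein genes, 12 rose and 8 fell, with none at 2-fold, and of 9 nuclear-retained and small RNAs, 3 rose and 5 fell.

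Reads may be shared for several other named genes, since from 26.5% to 35.8% of the windows of TAP2, AXIN2, RRM2, TGFB2 and AKR1C1 occur in other genes. From 20.6% to 22% of the exonic bases of IL6, IRF1, CRYAB and SQSTM1 are overlapped on the other strand.

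Besides the fibroblast markers given above, the lists of markers of other cell types did not pass camera. Higher and lower counts were 5 and 2 of 12 epithelial markers, 3 and 3 of 9 endothelial, 1 and 1 of 5 measured blood, and 3 and 2 of 9 neural or embryonic kidney line markers. The keratin genes KRT7 and KRT17 rose 2.04-fold and 1.73-fold and were expressed in the controls at 429 and 574 CPM. In 10 of the 32 uncalled lists the median, the mean and the test differed in sign. Adjusted over the list alone, the counts were the same or changed by 1 in all lists except the mitochondrial mRNAs, where 12 fell in place of 10. No list passed with an estimated correlation, whereas fry called 24 of 44 lists on balance in a direction, all 12 of the lists above among them.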

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

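The test against a 1.5-fold change and the upper-quartile scaling of the lists were chosen after the data were seen. Among 7942 calls (4153 higher, 3789 lower), the count stayed within 1.5 times under RLE, library-total and upper-quartile scaling, no filter, a mean CPM of at least 5, removal of the 20 most abundant genes and limma-voom (6516 to 8043). Upper-quartile factors and library totals gave 38.0% and 39.0% higher genes in place of 52.3%. DESeq2 called 5309 genes, with 2338 lower and 779 at least 2-fold lower, and 5305 of its calls were shared with edgeR; the cause was not tested. With a mean CPM of at least 5, 117 genes were at least 2-fold higher and 358 lower. Fewer genes were tested there, and the scaling was fitted again on them. MN1 stood at -0.35 in that run, and the called genes were 3245 higher and 3271 lower. The part each change of setting played was not tested. Against a 1.5-fold change, 1173 genes passed (358 higher, 815 lower; 209 and 692 at least 2-fold), and MN1 (-0.30) no longer did. Leaving out each library, with the lone library assumed to vary like the other group, gave 5991 to 6685 calls, 3372 to 3668 higher, 2619 to 3017 lower, 281 to 311 at least 2-fold higher and 837 to 1076 at least 2-fold lower. MN1 kept its call in these fits, at -0.32 to -0.26, and called lists numbered 12 to 19, the last without anti-MN1 replicate 1. With the replicate block the count was 7879, with 17 lists and MN1 at -0.30; no label says that a number marks a shared day or culture, and the deviations of same-numbered libraries from their group means correlated at -0.0031 across genes. In place of 12 lists, no filter called 22, an estimated correlation 0, fry 24 in a direction and 44 mixed. The cause was not tested, except that fry compares a list with no other genes. The loss with an estimated correlation need not come from the correlation itself. The NRF2 list had an estimate of -0.0362, under the preset 0.01. Its unadjusted camera p still went from 3.97e-15 to 0.0134. Over the scalings, no filter, the block, the left-out libraries, the estimated correlation and fry's directional test, the 12 called lists kept their direction, and among these lost their call with an estimated correlation alone; the lists were not run under the other settings. The gap between the mean correlation within groups and the highest between groups was 0.0172, and 0.0306 for genes with a mean CPM of at least 5. Of 2772 alternative values of 199 other genes, 115 lost the call, 98 of them against a 1.5-fold change, 1 gained it and 0 changed direction. In simulated data with few changed genes, depth limited the calls of low genes. Of the genes changed 1.5-fold, 41 of 61 were called there, against 39 of 45 at a mean CPM of at least 5.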

Other observations

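The family tests, and for the interferon-stimulated genes those of scaling and of blood cells, for the lower genes that of the loss per gene, and that of the origin of the libraries, were chosen after the results were seen. Every gene family with at least 8 tested protein-coding members and a shared symbol stem was tested with camera, 235 families in all. Of these, 21 passed at the preset correlation of 0.01 and 0 with an estimated correlation (adjusted p = 0.93 for the leading families). The clustered protocadherins, neuronal adhesion genes on chromosome 5 between 140786136 and 141512981, were not tested as 1 set. Of 44 tested members of the A, B and G clusters, 35 fell, 0 rose and 44 had a negative fold change, with a median of -1.24. The A and B families were among the 21 that passed (11 of 11 and 11 of 12 fell), and no family of the G cluster was. PCDHB5, the most abundant of the B cluster, went from 38.0 to 9.74 CPM, and PCDHB8, PCDHB11 and PCDHA6 had log2 fold changes of -1.84, -2.14 and -1.78. The A and G cluster genes share their last exons, so their counts are uncertain.

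Several of the other families that passed at the preset correlation were higher by small amounts, and each lost its call with an estimated correlation (adjusted p = 0.93). They were not tested together, and the fixed list nearest to some of them, cytosolic ribosomal proteins, did not pass (12 of 40 rose and 8 fell, camera adjusted p = 0.33). All 8 RRP genes and 9 of 11 UTP genes, which encode rRNA processing factors, rose, with medians of 0.41 and 0.43. Of 49 large-subunit mitochondrial ribosomal protein genes, 30 rose and 2 fell, and of 34 DDX helicase genes, 21 rose and 3 fell. Proteasome regulatory subunits (PSMD) had 12 of 14 higher and nucleoporins (NUP) 14 of 22.

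Interferon-stimulated genes rose by a median of 1.53 on the log2 scale. The choice among 4 scalings changed this little, with a lowest median of 1.44. These scalings moved the median of all genes only between -0.0038 and -0.089, so they could not have removed such a rise. The 19 fixed blood markers summed to 1.57 times the control, and to 0.681 times without LCP1, which was left out after its rise was seen, so blood or immune cells stay open, as LCP1 is expressed in the controls and most other markers lie near the floor. The 22 interferon genes had 35 and 23 counts (58 together) in the anti-MN1 libraries and 31 and 25 in the controls, mostly from IFNE, and IFNB1 had 0 in each library, which allows up to 0.187 and 0.188 CPM in the anti-MN1 libraries. An effect of the antibody's target and a difference in delivery or purity of the 2 antibody preparations may each give such a rise, and they cannot be told apart with 1 control antibody and no untreated cells.

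Genes at least 2-fold lower (1198) outnumbered those 2-fold higher (334), and among called genes 59 long intergenic non-coding RNAs were higher and 240 lower, against 3951 and 3094 protein-coding genes. A single scaling factor per library is argued against, with a lowest ratio of lower to higher calls of 3.59 over 4 scalings. Depth is argued against too. Thinned to 15740268 counts, the lower control still had 1.05 times the genes detected in the higher anti-MN1 library (28203 and 26871). The balance turned with level, however. At a mean of 1 to 5 CPM, 132 genes were at least 2-fold higher and 596 lower, against 13 and 7 at 100 CPM or more. The median log2 fold change went from -0.30 under 1 CPM to 0.10 at 100 CPM or more. The cause of this trend was not tested, and 1 factor per library cannot remove it. Olfactory receptor genes, 389 in number and taken as silent, held 680 counts in the controls and 451 in the anti-MN1 libraries, a ratio of shares of 0.674 (95% interval 0.597 to 0.760, counting error only). A few of them held most of these counts and may not be silent. The 381 genes with at most 20 counts held 225 and 140, a ratio of 0.632 (95% interval 0.508 to 0.784). Stray reads, such as from genomic DNA, may therefore add to the genes detected in the controls. For the 2-fold calls they are too few, since reads at the rate of all 389 genes make up a median of 0.832% of the loss. Such reads make up most of the loss in 0 of 1198 genes. This leaves a change in the cells and a difference in RNA quality or library preparation open and untested.

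Of the tested genes, 45.3% passed the threshold. Different chromosome copy numbers in the cells of the groups are argued against as the source of the direction of most calls. Centring each of 278 windows of 10 Mb on its median left 98.0% of the calls. A call was kept if its sign held and its ratio of fold change to error reached the lowest among the calls. That bar is lenient and the centred changes were not tested again, so how many would still pass is not known. A single window, chromosome 14 from 10 to 20 Mb with 22 genes, mostly pseudogenes and non-coding RNAs near the centromere, had a median of -1.50, beyond the highest of 1000 shuffles (0.725). That limit was the same for windows of any size, so smaller shifts of a region could not pass it. Every tested window of chromosome 22, where MN1 lies, was lower, with medians from -0.30 to -0.14. Those of chromosome 5 between 0 and 50 Mb were higher, from 0.19 to 0.30. Copy number changes of such regions stay open. GC content and transcript length are argued against too, as they explained 1.36% of the variance of the fold changes. The coefficient of variation between libraries beyond sampling was 3.34%, and whether the libraries of a group come from 1 culture, which would make small changes pass by shared handling, cannot be told apart from a true response because no label gives their origin.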
